A study of Mus musculus with 10 samples.

How the data were processed

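The 10 libraries were prepared from dendritic cells of mouse spleen. Per the labels' protocols, spleens of individual mice on a C57BL/6 background were digested with enzymes, CD11c-positive cells were enriched on beads, and cells high for MHC class II and CD11c were sorted by flow cytometry as CD11b-positive CD8-negative or CD11b-negative CD8-positive. Per the labels, the mice were 16 weeks old and either wild type (WT) or knockout (KO) for Atg16l1, a gene needed to attach LC3 to the autophagosome membrane. Per the labels' protocols, RNA was extracted on columns with a DNase step and made into strand-specific libraries from total RNA with a kit for small inputs.

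Per the submitters' processing notes, reads were aligned to GRCm38 with STAR 2.5.0a. The deposited values are raw counts per gene, with 53379 genes in each file and 4 further lines for reads given to no gene. Each file holds the counts without regard to strand and the counts for each strand. The annotation release, trimming and handling of duplicate reads are not stated in the labels. The sum over genes of the strand column used was 16.1 times that of the opposite strand, and a ratio of at least 3 had been required. Gene symbols and positions came from the GENCODE annotation of GRCm38, in which 53274 of the 53379 gene identifiers were found and 105 were not.

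Groups followed the labels for subset and genotype and were kept as labelled throughout. The 10 libraries had 9467704 to 13768884 gene counts each, out of 27495783 to 34289259 reads. Reads that mapped to more than 1 place (21.73% to 25.53% of reads) were not counted to any gene, so values of genes with near-identical copies, such as guanylate-binding proteins, histones and immunoglobulin segments, rest on the unique part of each gene. The libraries carry no molecular identifiers, so counting intervals and floors cover counting error only.

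CPM values, gene counts relative to the total of a library, were computed from the deposited counts with TMM-scaled library sizes. Genes were filtered with edgeR's filterByExpr by group, which left 14528 genes. A quasi-likelihood model with 4 group means was fitted to all 10 libraries in edgeR 4.0.16 (common dispersion 0.086, 6 residual and 16.1 prior degrees of freedom). The comparisons were KO against WT within each subset label, the difference of these genotype effects, and the label CD11b against the label CD8 within WT and within KO. P-values were adjusted by Benjamini-Hochberg within a comparison and called under 0.05. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. A fold against a group with no counts is given as a lower bound, with 3 counts over the group as the floor, and a ratio to a group with 1 to 3 counts carries its 95% counting interval.

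For each of the first 4 comparisons, 33 gene lists (749 entries, of which 747 matched a gene by symbol, 1 by synonym and 1 not) were tested two-sided with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, each adjusted over the lists. Counts of called members are given over all genes and adjusted over the list alone. The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule, Atg16l1 was named in every comparison. The 10 called genes with the largest log2 fold change in each direction were named, if they had a symbol other than that of a predicted model, a mean of at least 1 CPM and groups that did not overlap. For the difference of the genotype effects, the 5 genes with the smallest adjusted p in each direction were named, or the 5 with the smallest p where fewer than 5 passed. From each list described at most 4 members could be named, those with the smallest p, and some genes that the rule allows are not reported here.

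Alternatives were RLE size factors, no filter on low counts, a filter at 1 CPM in 3 libraries, unstranded counts, removal of mitochondrial and ribosomal RNA genes, DESeq2 1.42.0, limma-voom (limma 3.58.1) with quality weights, each library left out in turn, fits restricted to the libraries compared, and blocks on the replicate number. Leaving out both CD11b WT 1 and CD8 KO 2, and removal of immunoglobulin genes, were added after the data were seen. R 4.3.3 and Python 3.11.15 were used. The edgeR model was tested on simulated counts in which 2-fold changes were recovered in 48.4% of changed genes for KO against WT at the label CD11b (13827 genes tested), in 42.9% at the label CD8 (13823 genes), in 21.2% for the difference of effects (13803 genes) and in 48.4% for the subset comparison in WT (13801 genes). Unchanged genes made up 8 of 101 calls (7.9%), 4 of 82 (4.9%), 0 of 47 and 6 of 95 (6.3%) in these comparisons. The first 3 of these totals compare with 21, 21 and 3 calls in the data. More calls loosen the adjusted threshold, so recovery in those 3 comparisons may be lower in the data than in the simulation. Camera called a list of 25 genes shifted 1.5-fold in each of the 4 simulated comparisons and none of the other 33 lists. The simulated genes varied independently of each other, so these runs do not test the preset correlation on lists of genes that vary together. With an estimated correlation camera missed the shifted list in the difference of effects (adjusted p = 0.0856) and in the subset comparison in WT (0.0914).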

Results

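Gene expression was measured by RNA sequencing in dendritic cells sorted from the spleens of mice with or without Atg16l1, in a series on autophagy-deficient dendritic cell subsets and atherosclerosis. The 10 libraries fell into 4 groups by label: CD11b WT (n = 3), CD11b KO (n = 2), CD8 WT (n = 3) and CD8 KO (n = 2). Libraries are named here by label and number. Gene counts were 12950732, 13768884 and 10984712 in CD11b WT 1 to 3, 10037370 and 12289377 in CD11b KO 1 and 2, 9467704, 11081423 and 10444692 in CD8 WT 1 to 3, and 11787504 and 10964191 in CD8 KO 1 and 2. The number of genes with a count ranged from 16652 to 20918, with the highest number in CD11b WT 1, also when all libraries were thinned to 9467704 counts (20303 genes). The first principal component held 48% of the variance and separated the subset labels, with scores of −73.5 to −63.1 for the label CD11b and 63.8 to 72.0 for the label CD8. The correlation of log CPM between libraries of a group was 0.946 to 0.958.

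Atg16l1 (ENSMUSG00000026289, chromosome 1, 87755870 to 87792428), which encodes the scaffold that directs LC3 lipidation during autophagy, was the targeted gene and was low in each KO library. It stood at 13.3 to 32.7 CPM in the 6 WT libraries and at 1.73 to 3.31 CPM in the 4 KO libraries. At the label CD11b the means were 23.3 ± 9.70 CPM (SD, n = 3) in WT and 2.43 ± 0.845 CPM (SD, n = 2) in KO, a log2 fold change of −3.27 ± 0.41 (SE; edgeR adjusted p = 9.96e-05). At the label CD8 the means were 17.4 ± 2.17 CPM (SD, n = 3) and 2.52 ± 1.12 CPM (SD, n = 2), a log2 fold change of −2.79 ± 0.40 (SE; edgeR adjusted p = 0.00132). The genotype labels matched the targeted gene in 10 of 10 libraries. With limma-voom the adjusted p at the label CD11b was 0.0654. Which part of the gene was deleted is not stated in the labels.

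The subset labels ran opposite to the subset markers in 10 of 10 libraries. Cd8a, which encodes the CD8 alpha chain, stood at 448 to 578 CPM in the libraries labelled CD11b and at 0.905 to 5.87 CPM in those labelled CD8. Xcr1 and Clec9a, a chemokine receptor and a dead-cell receptor of type 1 conventional dendritic cells (cDC1), reached 290.0 to 442 CPM and 541 to 667 CPM at the label CD11b, against 7.14 to 11.3 CPM and 25.5 to 40.8 CPM at the label CD8. Itgam, which encodes CD11b, stood at 1.58 to 2.73 CPM in the libraries labelled CD11b and at 76.1 to 104 CPM in those labelled CD8. Sirpa, an inhibitory receptor of type 2 conventional dendritic cells (cDC2), stood at 23.9 to 29.2 CPM at the label CD11b and at 553 to 629 CPM at the label CD8. The mean log2 CPM of the cDC1 markers was 7.95 to 8.16 at the label CD11b and 4.41 to 4.98 at the label CD8, while that of the cDC2 markers was 3.60 to 3.92 and 6.36 to 6.57. By these transcripts, the libraries labelled CD11b held cells with cDC1 markers and those labelled CD8 held cells with cDC2 markers. The labels were kept as given, so each direction that follows is between libraries labelled CD11b or CD8 and does not name the cell type sorted.

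**Figure D1:**
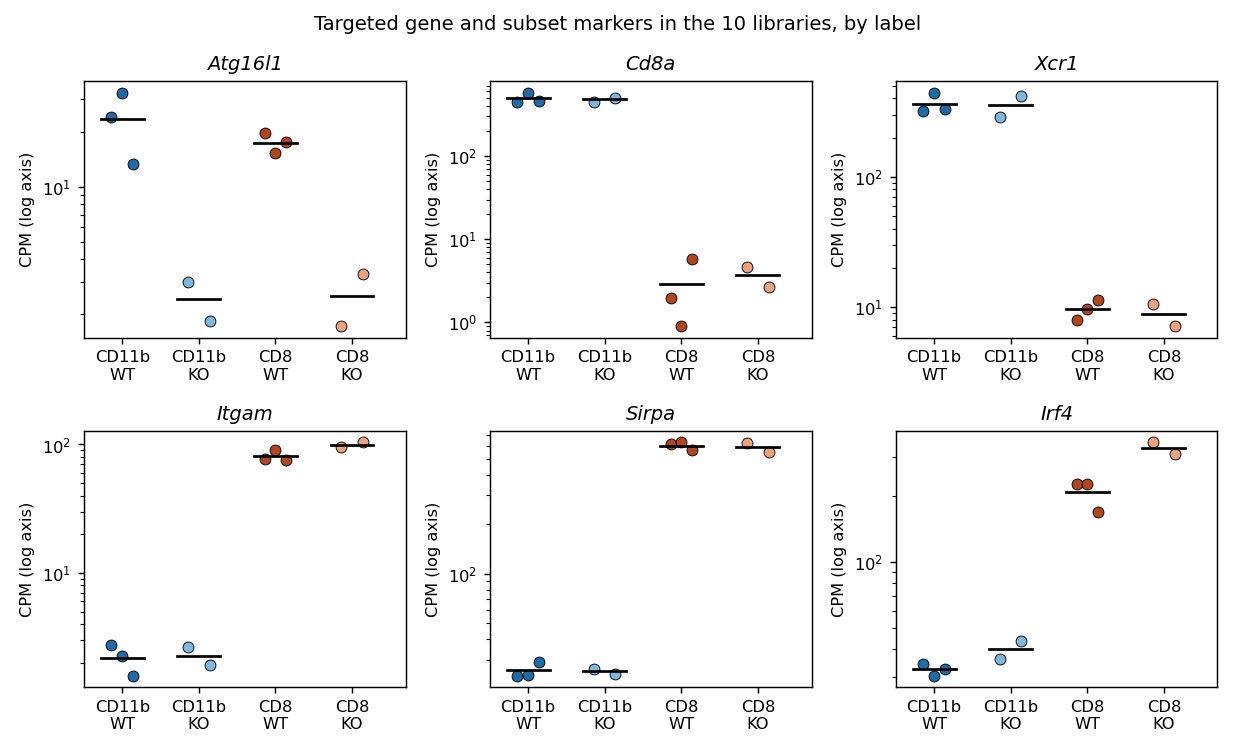
Atg16l1 and 5 subset markers in CPM (log axes) by labelled group, with 1 point per library and a line at the group mean. Atg16l1 is lower in all 4 KO libraries, and Cd8a and Xcr1 are high in libraries labelled CD11b while Itgam, Sirpa and Irf4 are high in libraries labelled CD8.

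The comparison of KO with WT at the label CD11b asks what loss of Atg16l1 changes in 1 of the subsets. A peptide transporter and 3 neighbouring guanylate-binding proteins were lower in KO, with the 4 smallest p of the genes called. Slc15a2 (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962), which encodes the transporter PEPT2 for di- and tripeptides, fell from 75.6 ± 3.99 CPM (SD, n = 3) to 0.336 ± 0.239 CPM (SD, n = 2), with 5 and 2 counts in the KO libraries. Gbp2b, Gbp3 and Gbp2, interferon-inducible GTPases encoded side by side on chromosome 3 (142560026 to 142638008), fell from 158 ± 46.9, 94.2 ± 17.5 and 84.7 ± 12.9 CPM (SD, n = 3) to 3.83 ± 2.00, 8.14 ± 2.52 and 10.9 ± 2.59 CPM (SD, n = 2). Itgad, which encodes the integrin alpha D chain next to Itgax, rose from 2.66 ± 1.64 to 19.5 ± 4.15 CPM. Odc1, the first enzyme of polyamine synthesis, fell from 160 ± 11.3 to 79.7 ± 8.25 CPM.

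With edgeR, 21 of 14528 genes were called at the label CD11b, 8 higher and 13 lower in KO. The log2 fold change was −7.83 ± 0.32 (SE) for Slc15a2 (edgeR adjusted p = 2.99e-13), −5.39 ± 0.37 for Gbp2b (5.88e-09), −3.52 ± 0.25 for Gbp3 (6.25e-09), −2.95 ± 0.23 for Gbp2 (3.41e-08) and 2.85 ± 0.36 for Itgad (9.96e-05). Odc1 had −1.001 ± 0.142 (edgeR adjusted p = 0.000644) and Arhgef6, an exchange factor for Rac and Cdc42, −1.30 ± 0.16 (9.96e-05). Cd300a, an inhibitory receptor for phosphatidylserine, fell by 1.02 ± 0.17 on the log2 scale (edgeR adjusted p = 0.00700). Tnfsf9, the ligand of the costimulatory receptor 4-1BB, had −1.62 ± 0.30 (edgeR adjusted p = 0.0194), and the kinase gene Tesk2 had −4.01 ± 0.79 (0.0288). Tesk2 was low in both groups, at 3.08 CPM in WT and 0.175 CPM in KO. Among higher genes, Ighg3, an immunoglobulin heavy chain constant gene, rose from 0.208 ± 0.152 to 8.04 ± 1.47 CPM, with a log2 fold change of 5.16 ± 0.64 (SE; edgeR adjusted p = 9.96e-05). The light chain joining segment Igkj1 had 68 counts in KO against 3 in WT, a ratio of 38.5 (95% counting interval 12.6 to 191; edgeR adjusted p = 0.0152). Ceacam16 and Sbk1 had log2 fold changes of 2.36 ± 0.45 and 2.26 ± 0.44 (edgeR adjusted p = 0.0266 and 0.0277). Both were low at this label, at 0.588 and 0.958 CPM in WT and 3.00 and 4.55 CPM in KO. In CD8 WT they stood at 23.7 and 16.1 CPM. Slc15a2 had −8.73 without CD11b KO 1 and −7.20 without CD11b KO 2, and Gbp2b −6.02 without CD11b KO 1. Without CD11b WT 1 Itgad had 3.51 and Ighg3 5.90, without CD11b WT 2 Igkj1 had 5.85, and without CD11b KO 2 Sbk1 had 1.61 and Tesk2 −4.79. The count of 21 ranged from 14 (without CD11b WT 1) to 27 (without CD11b WT 2) with 1 WT library left out. Leaving out 1 KO library left a group of 1, and the filter then kept 16842 to 17062 genes against 14528. Counts of calls from those fits are therefore not compared with 21. Calls ended for Igkj1 without CD11b WT 1 or 3 (edgeR adjusted p = 0.0751, 0.0576) and for Ceacam16 without CD11b WT 1 or 2, CD11b KO 1 or CD8 WT 2 (0.0685, 0.0663, 0.082, 0.0684). That of Sbk1 ended without CD11b WT 1, 2 or 3 or CD11b KO 2 (edgeR adjusted p = 0.0953, 0.11, 0.0576, 0.313). Tesk2 lost its call without CD11b WT 1 or 2, CD11b KO 1 or 2 or CD8 WT 1 or 2 (edgeR adjusted p = 0.0751, 0.0533, 0.284, 0.0897, 0.0582, 0.0684), and Tnfsf9 without CD11b WT 1 or CD11b KO 2 (0.0672, 0.207). With limma-voom the calls of Ighg3 and Cd300a ended as well (limma adjusted p = 0.542 and 0.316).

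Among the gene lists, 5 of 33 were called by camera at the label CD11b, all lower in KO, and 0 held with an estimated correlation (1 at an unadjusted p under 0.05) or with fry (3 at an unadjusted p under 0.05). Of 40 interferon-response genes measured, 2 fell (2 adjusted over the list alone), namely Gbp3 and Gbp2, and the list's median log2 fold change was −0.12 (camera adjusted p = 0.00114; adjusted p = 0.574 with an estimated correlation). Other members of that GTPase family, named after their values were seen, did not pass, with log2 fold changes of −0.16 for Gbp4, −0.53 for Gbp5, −0.44 for Gbp7, 0.27 for Gbp8 and −0.22 for Gbp9. Of 25 cDC2 markers, 2 fell (4 adjusted over the list alone), Cd300a and the decoy receptor gene Il1r2 (−0.57 ± 0.11 SE, edgeR adjusted p = 0.0296). Both were lower at this label than at the label CD8 to begin with. Il1r2 stood at 43.5 to 55.3 CPM in CD11b WT against 613.5 to 650 CPM in CD8 WT. Tmem176a (−0.71) and Cd209a (−1.26) passed over the list alone. The median of the cDC2 markers was −0.25, or −0.23 with genes at their bound (camera adjusted p = 8.31e-05; adjusted p = 0.572 with an estimated correlation). Of 24 immediate early genes, a class that responds to tissue dissociation, 0 were called by edgeR, DESeq2 or limma-voom (1 lower adjusted over the list alone, Fosb at −0.36; 7 at an unadjusted p under 0.05). All 24 had a negative log2 fold change, with a median of −0.25 (camera adjusted p = 5.39e-06; adjusted p = 0.574 with an estimated correlation). Of 24 cytokine and chemokine genes, 0 were called by edgeR, DESeq2 or limma-voom (0 adjusted over the list alone; 4 at an unadjusted p under 0.05). Ccl6, Ccl4 and Il1b had log2 fold changes of −0.69, −0.50 and −0.29, and the list a camera adjusted p of 0.0108 (adjusted p = 0.574 with an estimated correlation). Of 38 cell cycle genes, 0 were called by edgeR, DESeq2 or limma-voom (0 adjusted over the list alone; 6 at an unadjusted p under 0.05). Nusap1 and Mcm7 had log2 fold changes of −0.59 and −0.40, and the list a camera adjusted p of 0.0216 (adjusted p = 0.657 with an estimated correlation). Of 24 costimulation and checkpoint genes, 1 fell, Tnfsf9 (1 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.969), and the median of 0.03 and mean of 0.30 went against the test's downward direction, with a fitted 5.12 in that mean for Cd276 (8 counts in KO, 0 in WT). Of 34 core autophagy genes, 1 fell, Atg16l1 itself (1 adjusted over the list alone), while Map1lc3b, which encodes LC3B, had 0.41 (edgeR adjusted p = 0.800; camera adjusted p = 0.409 for the list). Of 15 B cell markers, 0 were called by edgeR, DESeq2 or limma-voom (0 adjusted over the list alone; 3 at an unadjusted p under 0.05), with a median of 0.20, a mean of −0.01 and an upward test direction (camera adjusted p = 0.563). List calls ended for the interferon-response genes without CD11b WT 3 or CD11b KO 1 (camera adjusted p = 0.367, 0.092), for cytokines and chemokines without CD11b WT 2 or CD11b KO 1 (0.155, 0.12) and for the cell cycle without CD11b WT 3 or CD11b KO 1 (0.38, 0.12). The call of Il1r2 ended without any 1 of CD11b WT 1 or 2, CD11b KO 1 or 2, or CD8 WT 1, 2 or 3 (edgeR adjusted p = 0.142, 0.0557, 0.152, 0.0897, 0.0582, 0.071, 0.0508), and that of Tnfsf9 without CD11b WT 1 or CD11b KO 2 (0.0672, 0.207).

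At the label CD8, KO was compared with WT to ask the same question in the other subset. A phospholipase and the integrin alpha D chain were higher in KO, and the peptide transporter was again lower. Plcb4, a phospholipase C that acts downstream of G protein-coupled receptors, rose from 11.9 ± 3.35 CPM (SD, n = 3) to 124 ± 0.608 CPM (SD, n = 2). Itgad rose from 6.43 ± 3.04 to 78.8 ± 7.25 CPM, and Irf4, a transcription factor of cDC2, from 208 ± 33.4 to 329.7 ± 28.9 CPM. Slc15a2 fell from 105 ± 8.83 to 1.16 ± 0.704 CPM. Mmp9, which encodes gelatinase B, fell from 25.6 ± 6.34 to 3.89 ± 0.0854 CPM, and Odc1 from 57.9 ± 7.50 to 20.2 ± 2.91 CPM.

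With edgeR, 21 of 14528 genes were called at the label CD8, 9 higher and 12 lower in KO (32 higher and 22 lower with DESeq2). The log2 fold change was 3.39 ± 0.18 (SE) for Plcb4 (edgeR adjusted p = 2.35e-11), 3.63 ± 0.34 for Itgad (1.03e-06), 1.02 ± 0.16 for Lima1, an actin-bundling protein (0.00325), and 0.67 ± 0.13 for Irf4 (0.0269). Slc15a2 had −6.51 ± 0.27 (edgeR adjusted p = 2.60e-13), Gbp2b −3.19 ± 0.48 (0.00205), Mmp9 −2.71 ± 0.41 (0.00211), Odc1 −1.52 ± 0.15 (4.19e-06) and Arhgef6 −1.03 ± 0.16 (0.00211). Gcnt2, which branches glycan chains, fell by 0.64 ± 0.10 and Fkbp15 by 0.68 ± 0.13 on the log2 scale (edgeR adjusted p = 0.00211 and 0.0189). Cox6a2, a subunit of cytochrome oxidase, rose from 0.272 ± 0.470 to 7.41 ± 2.09 CPM, with 9 of its 9 WT counts in CD8 WT 2 (log2 fold change 4.65 ± 0.93 SE, edgeR adjusted p = 0.0372); it lies within the span of Itgad on the other strand, where the 4 KO libraries held 58 counts against 273 on its own. Hist1h4b, Gfod1 and Cyb5r4 had log2 fold changes of 1.02 ± 0.20, 0.64 ± 0.11 and −0.89 ± 0.18 (edgeR adjusted p = 0.0269, 0.0114 and 0.0416). Without CD8 KO 1 Slc15a2 had −5.98 and Gbp2b −4.14, and without CD8 KO 2 Slc15a2 had −7.295. The count of 21 ranged from 18 to 30 with 1 WT library left out. Fits without 1 KO library tested 16842 to 17062 genes against 14528, so their counts of calls are not compared with 21. Calls ended for Cox6a2 without CD8 WT 1 or 3 or CD8 KO 2 (edgeR adjusted p = 0.0925, 0.165, 0.0903) and for Hist1h4b without CD8 WT 1, 2 or 3 or CD8 KO 2 (0.0841, 0.0865, 0.109, 0.197). Irf4 lost its call without CD8 WT 3 or CD8 KO 1 (edgeR adjusted p = 0.165, 0.0959) and Gfod1 without CD8 WT 1 or CD8 KO 2 (0.0603, 0.246). The call of Cyb5r4 ended without CD11b WT 3, CD8 WT 1 or 3 or CD8 KO 2 (edgeR adjusted p = 0.0706, 0.103, 0.174, 0.435) and that of Fkbp15 without CD8 WT 1 or 2 (0.0634, 0.0976). With limma-voom the call of Gbp2b ended (limma adjusted p = 0.41).

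Marker lists of other cells differed with genotype at the label CD8 by camera. Of 15 B cell markers, 0 were called by edgeR or DESeq2 and 2 by limma-voom (12 higher adjusted over the list alone; 12 at an unadjusted p under 0.05), and 15 of 15 had a positive log2 fold change. The median was 1.28 (camera adjusted p = 2.33e-12; adjusted p = 0.325 with an estimated correlation). Cd79a, Igkc and Ighm had log2 fold changes of 1.63, 1.55 and 1.31, and of −0.04, 0.51 and 0.52 without CD8 KO 2. CD8 KO 2 held the most of these transcripts, with 43.7 CPM of Cd79a against 8.15 CPM in CD8 KO 1, and without CD8 KO 2 the camera adjusted p was 0.794. Of 16 red pulp macrophage markers, 0 were called by edgeR or DESeq2 and 2 by limma-voom (3 higher adjusted over the list alone; 5 at an unadjusted p under 0.05). The complement genes C1qa and C1qb had log2 fold changes of 0.99 and 0.89, and the list, higher in KO, a camera adjusted p of 6.74e-05 (adjusted p = 0.172 with an estimated correlation). Of 3 neutrophil markers measured, 1 fell, Mmp9 (1 adjusted over the list alone, camera adjusted p = 0.0052, adjusted p = 0.172 with an estimated correlation). The list's call did not hold without CD8 KO 1. Most neutrophil markers listed did not pass the filter, among them S100a8 with 2 counts in CD8 WT 3 and 0 in each other library. The list therefore says little about neutrophils. Of 12 monocyte markers, 0 were called by edgeR, DESeq2 or limma-voom (0 adjusted over the list alone; 3 at an unadjusted p under 0.05). Fn1 had a log2 fold change of −1.34, and the list, lower in KO, a camera adjusted p of 0.0381 (adjusted p = 0.294 with an estimated correlation). That call ended without CD8 WT 2, CD8 KO 1 or CD8 KO 2 (camera adjusted p = 0.0709, 0.0784, 0.0816). Of 14 plasmacytoid dendritic cell markers, 1 rose, Cox6a2 (2 adjusted over the list alone), while the list's median was −0.07, or −0.06 with genes at their bound, against a mean of 0.22 and an upward test direction (camera adjusted p = 0.685).

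Among 33 lists at the label CD8, 10 were called by camera, 7 higher in KO (B cell, red pulp macrophage, LXR, mature dendritic cell, cytokine, NRF2 and MHC class I lists) and 3 lower, and 0 held with an estimated correlation (5 at an unadjusted p under 0.05) or with fry (6 at an unadjusted p under 0.05). Of 27 genes of LXR targets and lipid handling, 0 were called by edgeR, 1 by DESeq2 and 2 by limma-voom (4 higher adjusted over the list alone; 5 at an unadjusted p under 0.05). The 4 were Nr1h3, which encodes the sterol receptor LXR alpha (1.24), Scd1 (0.85, but 0.06 without CD8 KO 2), the lipoprotein gene Apoe (0.58) and the lipid droplet gene Plin2 (0.45), with camera adjusted p = 0.00145 and adjusted p = 0.172 with an estimated correlation. Of 18 genes of mature and migratory dendritic cells, 0 were called by edgeR or limma-voom and 2 by DESeq2 (4 higher and 1 lower adjusted over the list alone; 7 at an unadjusted p under 0.05). Cacnb3, Serpinb6b, Il12b and Cd83 had log2 fold changes of 0.76, 0.70, 0.62 and −0.30, and the list a camera adjusted p of 0.000668 (adjusted p = 0.495 with an estimated correlation). Of 24 cytokine and chemokine genes, 0 were called by edgeR or limma-voom and 1 by DESeq2 (3 higher and 1 lower adjusted over the list alone; 6 at an unadjusted p under 0.05). Il6, Cxcl9 and Ccl6 had log2 fold changes of 2.80, 0.65 and −0.64, and the list a camera adjusted p of 0.0381 (adjusted p = 0.396 with an estimated correlation). Of 17 NRF2 targets, 0 were called by edgeR and 1 each by DESeq2 and limma-voom (1 adjusted over the list alone, the heme oxygenase gene Hmox1 at 0.74; 2 at an unadjusted p under 0.05; camera adjusted p = 0.0225; adjusted p = 0.341 with an estimated correlation). Of 22 MHC class I pathway genes, 0 were called by edgeR, DESeq2 or limma-voom (1 adjusted over the list alone, the transactivator gene Nlrc5 at 0.40; 2 at an unadjusted p under 0.05; camera adjusted p = 0.00976; adjusted p = 0.358 with an estimated correlation). Of 24 immediate early genes, 0 were called by edgeR, 1 by DESeq2 and 3 by limma-voom (5 lower adjusted over the list alone; 12 at an unadjusted p under 0.05). All 24 were negative, with a median of −0.29. Nr4a2, Fosb, Btg2 and Fos had log2 fold changes of −0.40, −0.35, −0.29 and −0.57, and the list a camera adjusted p of 7.87e-09 (adjusted p = 0.341 with an estimated correlation). Of 25 cDC2 markers, 1 rose, Irf4 (2 higher and 1 lower adjusted over the list alone, with 0.43 for Lyz2 and −0.65 for Tbx21; camera adjusted p = 0.268). Of 22 TGF-beta and retinoic acid genes, 0 were called by edgeR or limma-voom and 1 by DESeq2 (2 higher adjusted over the list alone, Smad3 at 0.80 and Tgfb3 at 1.72; 4 at an unadjusted p under 0.05; camera adjusted p = 0.287). Of 34 core autophagy genes, 1 fell, Atg16l1 (1 adjusted over the list alone; camera adjusted p = 0.647), with a median of 0.00, a mean of −0.07 and a downward test direction. Without CD8 KO 2 the calls of the LXR and MHC class I lists ended (camera adjusted p = 0.113 and 0.113). That of NRF2 targets ended without CD8 WT 3 or CD8 KO 1 (camera adjusted p = 0.116, 0.153) and that of cytokines and chemokines without CD11b WT 3, CD8 WT 3 or CD8 KO 1 (0.0989, 0.305, 0.336). The call of Irf4 ended without CD8 WT 3 or CD8 KO 1 (edgeR adjusted p = 0.165, 0.0959).

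Of the 34 genes called at either label, 8 were called at both, and 8 of 8 had the same direction. Itgad and the predicted gene Gm11942 were higher, and Atg16l1, Slc15a2, Gbp2b, Odc1, Arhgef6 and Gcnt2 were lower in KO. The 2 shared higher genes compare with 0.005 for independent lists of these sizes and the 6 shared lower genes with 0.011. Atg16l1, the targeted gene, is among the 6. Mice that gave libraries of both labels are not excluded, and a difference between mice would then recur at both labels. The overlap is therefore not read as independent replication. Gm11942, named after its values were seen, stood at 0.0930 to 0.228 CPM and 0 to 0.0905 CPM in the WT libraries labelled CD11b and CD8 and at 16.5 and 20.1 CPM and 10.9 and 17.8 CPM in KO. Over 9655 genes with a mean of at least 2 log2 CPM, Spearman's rho between the fold changes at the 2 labels was 0.097; this is across genes, which are not independent replicates.

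**Figure D2:**
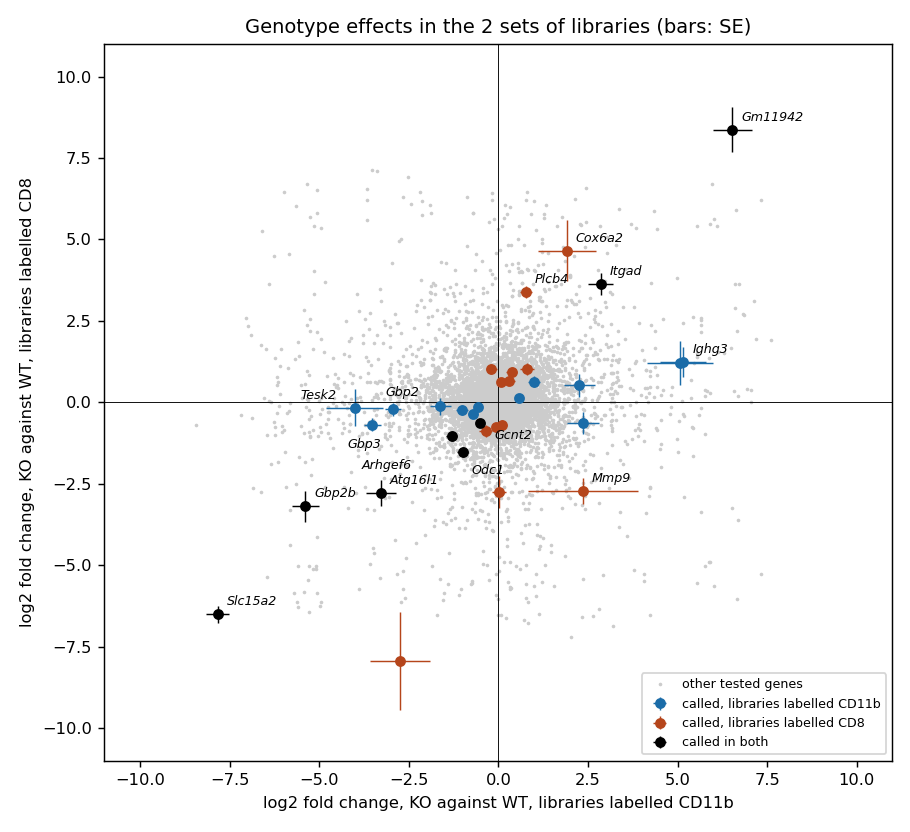
Log2 fold change of KO against WT in libraries labelled CD11b (x axis) and CD8 (y axis), with 1 point per tested gene and bars of 1 SE for called genes. The 8 genes called at both labels (black) share their direction. Positions are fitted values, and those of Gm11942 and of the unlabelled gene at the lower left, Gm34084, rest on a group with 0 or 1 counts. The x position of Mmp9 rests on 0 counts in CD11b WT and 1 in CD11b KO.

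**Figure D3:**
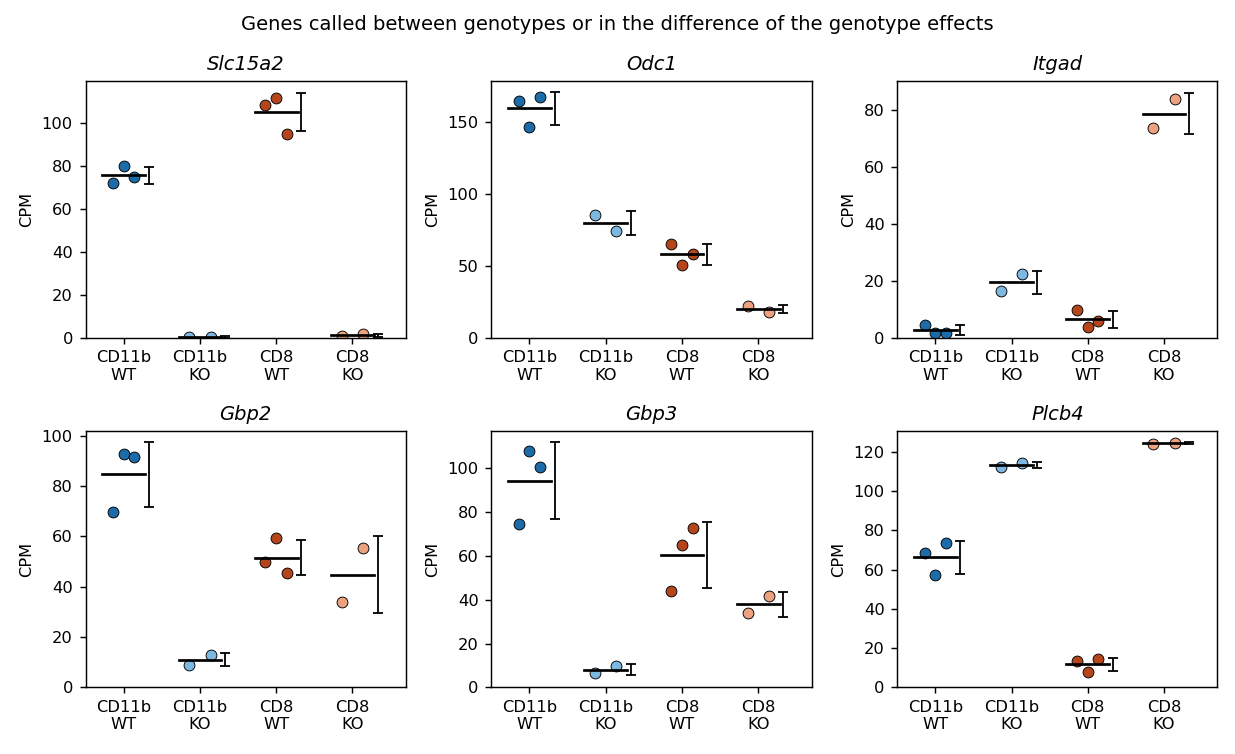
CPM of 6 called genes by labelled group, with 1 point per library, a line at the group mean and bars of 1 SD. Slc15a2, Odc1 and Itgad differ between WT and KO at both labels, Gbp2 and Gbp3 fall from 84.7 and 94.2 to 10.9 and 8.14 CPM at the label CD11b, and Plcb4 rises from 11.9 to 124 CPM at the label CD8.

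Itgad and Cox6a2 lie beside Itgax, which encodes CD11c, on chromosome 7. Over the 4 tested genes between Itgax and Armc5 (Itgad, Gm39091, 4931431B13Rik and Cox6a2), chosen after their values were seen and 3 of them within the span of Itgad, the median log2 fold change was 2.42 at the label CD11b and 4.14 at the label CD8. The 20 tested genes flanking them had medians of −0.05 and 0.14. Itgax itself had 0.01 and 0.35 (edgeR adjusted p = 0.994 and 0.175).

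**Figure D4:**
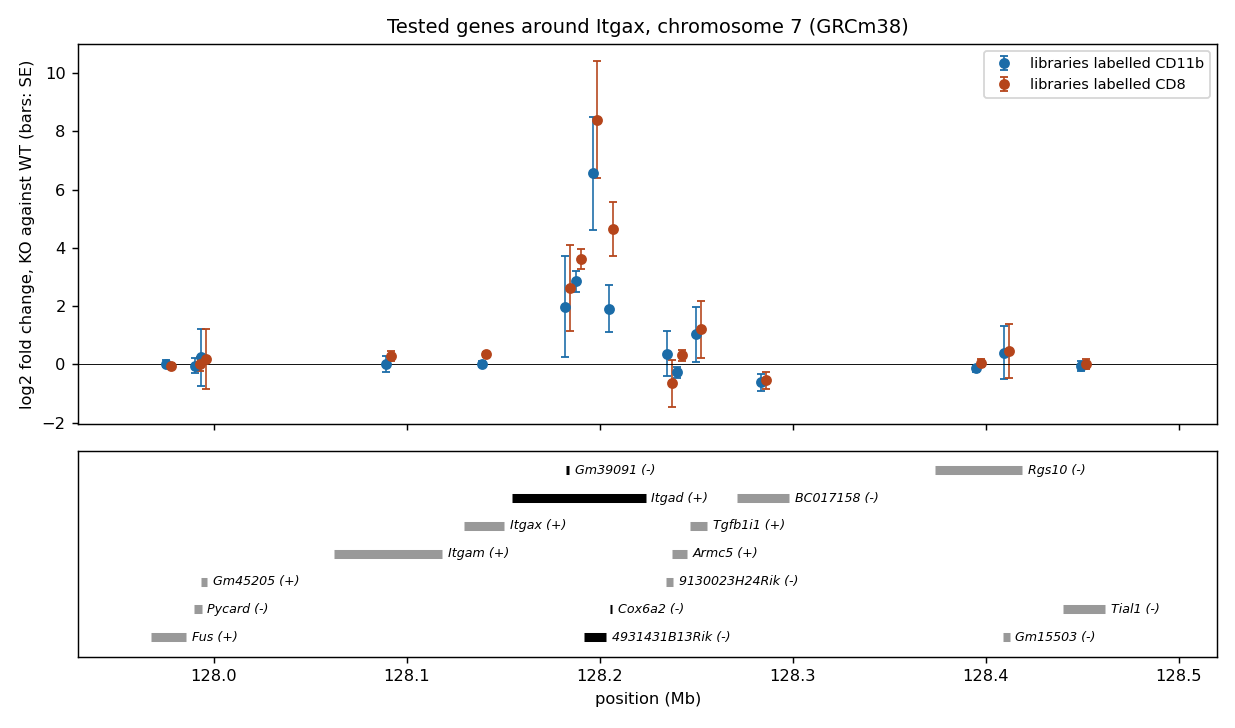
Log2 fold change of KO against WT (top, bars of 1 SE) and extent of the tested genes (bottom, strand in brackets) around Itgax on chromosome 7 of GRCm38, in Mb. The 4 genes drawn in black have medians of 2.42 at the label CD11b and 4.14 at the label CD8; the fitted value of 4931431B13Rik rests on WT groups with 0 counts.

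The difference between the genotype effects asks whether loss of Atg16l1 acts alike in the 2 sets of libraries. It differed for 2 guanylate-binding proteins and a phospholipase. Gbp2 fell at the label CD11b and stood at 51.6 CPM in WT and 44.8 CPM in KO at the label CD8 (edgeR adjusted p = 0.966), a difference of effects of −2.74 ± 0.29 (SE; edgeR adjusted p = 2.73e-05). Gbp3 stood at 60.5 and 37.8 CPM at the label CD8 (edgeR adjusted p = 0.365), a difference of −2.84 ± 0.31 (2.73e-05). Plcb4 stood at 66.4 ± 8.41 CPM (SD, n = 3) in WT and 113 ± 1.54 CPM (SD, n = 2) in KO at the label CD11b, where it missed the threshold (edgeR adjusted p = 0.053). Its difference of effects was −2.62 ± 0.24 (SE; edgeR adjusted p = 4.72e-06). These 3 were the genes called, all lower at the label CD11b relative to the label CD8, whereas DESeq2 called 6 higher and 5 lower. Apoe and Lima1 came next, with −1.004 ± 0.18 and −1.22 ± 0.22 (edgeR adjusted p = 0.0523 for both), and passed in 14 and 12 of 21 alternatives. The effect on Atg16l1 itself did not differ detectably (−0.49 ± 0.55 SE, edgeR adjusted p = 0.963). The count of 3 became 5 without CD11b WT 3, 6 without CD8 WT 1 and 5 without CD8 WT 3. Fits without 1 KO library tested 16842 to 17062 genes against 14528, so their counts of calls are not compared with 3.

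For this difference, 6 of 33 lists were called by camera, all lower, and 0 held with an estimated correlation (3 at an unadjusted p under 0.05) or with fry (3 at an unadjusted p under 0.05). Of 24 cytokine and chemokine genes, 0 were called by edgeR, DESeq2 or limma-voom (1 adjusted over the list alone; 5 at an unadjusted p under 0.05). Il12b, Ccl4 and Cxcl9 had log2 fold changes of −0.86, −0.76 and −0.69, and the list a camera adjusted p of 1e-04 (adjusted p = 0.283 with an estimated correlation). Of 27 LXR and lipid handling genes, 0 were called by edgeR and 1 each by DESeq2 and limma-voom (2 adjusted over the list alone; 6 at an unadjusted p under 0.05). Scd1 (−0.39 without CD8 KO 2) and the sterol exporter gene Abcg1 had log2 fold changes of −1.17 and −0.50, and the list a camera adjusted p of 0.00328 (adjusted p = 0.242 with an estimated correlation). Of 34 lysosomal genes, 0 were called by edgeR, DESeq2 or limma-voom (0 adjusted over the list alone; 5 at an unadjusted p under 0.05). Tpp1, Ctsb, Ctsh and Psap had log2 fold changes of −0.83, −0.39, −0.37 and −0.23, and the list a camera adjusted p of 0.0103 (adjusted p = 0.389 with an estimated correlation). Of 18 mature and migratory dendritic cell genes, 0 were called by edgeR, DESeq2 or limma-voom (3 adjusted over the list alone; 5 at an unadjusted p under 0.05). Apol7c and Serpinb6b had log2 fold changes of −0.69 and −0.62, and the list a camera adjusted p of 0.00229 (adjusted p = 0.598 with an estimated correlation). Of 25 cDC2 markers, 0 were called by edgeR, DESeq2 or limma-voom (3 adjusted over the list alone; 8 at an unadjusted p under 0.05). Tmem176a, Cd300a and Lyz2 had log2 fold changes of −0.82, −0.79 and −0.60, and the list a camera adjusted p of 0.0115 (adjusted p = 0.588 with an estimated correlation). Of 15 B cell markers, 0 were called by edgeR, DESeq2 or limma-voom (1 adjusted over the list alone; 5 at an unadjusted p under 0.05). Ms4a1 and Cd79a had log2 fold changes of −1.91 and −1.76 (−0.63 and −0.09 without CD8 KO 2), and the list a camera adjusted p of 6.15e-05 (adjusted p = 0.598 with an estimated correlation). Of 40 interferon-response genes, 2 were lower, Gbp2 and Gbp3 (2 adjusted over the list alone; camera adjusted p = 0.0571). Calls ended for LXR and lipid handling without CD8 KO 2 (camera adjusted p = 0.062) and for lysosomal genes without CD11b KO 1 (0.149). They also ended for mature and migratory genes without CD11b WT 2 or CD11b KO 2 (camera adjusted p = 0.248, 0.0547) and for cDC2 markers without CD11b WT 3, CD11b KO 1 or 2, CD8 WT 3 or CD8 KO 1 (0.0718, 0.126, 0.118, 0.0548, 0.291). The call of the B cell markers ended without CD11b KO 1 (camera adjusted p = 0.126) or CD8 KO 2 (0.897, with the direction turned).

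Comparing the label CD11b with the label CD8 in WT asks how the 2 sorted subsets differ without loss of autophagy. Cd8a and Itgae were higher at the label CD11b, and Cd101 at the label CD8. Cd8a stood at 496 ± 71.7 CPM (SD, n = 3) at the label CD11b against 2.91 ± 2.62 CPM (SD, n = 3) at the label CD8, a log2 fold change of 7.40 ± 0.29 (SE; edgeR adjusted p = 3.78e-15). Itgae, which encodes CD103, stood at 131 ± 39.7 against 2.07 ± 2.22 CPM (5.96 ± 0.35 SE; edgeR adjusted p = 2.85e-12). Cd101, an inhibitory immunoglobulin-family receptor, stood at 0.307 against 52.7 ± 7.23 CPM (−7.42 ± 0.38 SE; edgeR adjusted p = 6.98e-13).

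In this comparison 4285 of 14528 genes were called by edgeR, 1999 higher and 2286 lower at the label CD11b. Against a floor of 3 counts over the group at 0, Clec4b2 was at least 62.0-fold, Cd8b1 at least 52.0-fold, Naalad2 at least 26.3-fold, Chdh at least 23.8-fold and BC034090 at least 20.2-fold higher. The protease gene Pcsk5 had 575 counts against 1, a ratio of 477 (95% counting interval 85.4 to 18900). Gpr33 and Mab21l3 had log2 fold changes of 6.17 ± 0.64 and 6.13 ± 0.37 (SE; edgeR adjusted p = 4.50e-08 and 4.69e-12). In the other direction, Mmp9 was at least 314-fold, the activating receptor gene Trem1 at least 159-fold, Ffar1 at least 73.0-fold, Nxpe5 at least 61.0-fold, Sirpb1c at least 59.8-fold, Cd276 at least 47.8-fold, Ackr1 at least 45.8-fold and Grpr at least 20.9-fold lower. Slc44a5 had 201 counts at the label CD8 against 1 (ratio 242, 95% counting interval 43.0 to 9610). Atg16l1 did not pass (0.43 ± 0.30 SE, edgeR adjusted p = 0.33). In KO, the same comparison called 3312 genes, 1502 higher and 1810 lower. In both genotypes 2834 genes were called, 2832 of them in the same direction, and 97.5% of the WT calls had the same direction in KO.

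Of 33 lists, 12 were called by camera in this comparison, 4 higher and 8 lower at the label CD11b, and 4 held with an estimated correlation, while fry called 22. Of 22 cDC1 markers, 22 were higher (22 adjusted over the list alone), with a median of 3.46. Xcr1, Clec9a, Ppt1 and Naaa had log2 fold changes of 5.23, 4.13, 3.68 and 3.44, and the list a camera adjusted p of 2.53e-71 (adjusted p = 0.0023 with an estimated correlation). Of 25 cDC2 markers, 24 were lower and 1 higher (24 and 1 adjusted over the list alone), with a median of −3.15. Sirpa, Itgam, Il1r2 and the Notch regulator gene Dtx1 had log2 fold changes of −4.55, −5.19, −3.65 and −5.98, and the list a camera adjusted p of 2.87e-51 (adjusted p = 0.00167 with an estimated correlation). Of 27 inflammasome and NF-kappaB genes, 21 were lower and 1 higher (21 and 1 adjusted over the list alone). Nod1, Nfkbiz, Nfkbie and Nlrp3 had log2 fold changes of −2.63, −1.89, −1.87 and −1.75, and the list a camera adjusted p of 5.55e-16 (adjusted p = 0.0023 with an estimated correlation). Of 40 interferon-response genes, 28 were lower and 6 higher (30 and 6 adjusted over the list alone). The RNA sensor gene Ddx58, Oasl2, Ifi203 and Ifi205 had log2 fold changes of −5.16, −4.39, −3.10 and 2.52, and the list a camera adjusted p of 1.3e-10 (adjusted p = 0.128 with an estimated correlation). Of 22 MHC class I pathway genes, 12 were higher and 5 lower (12 and 5 adjusted over the list alone). Pdia3, Psme1, Psmb8 and Calr had log2 fold changes of 1.52, 0.99, 0.93 and 0.90, and the list a camera adjusted p of 0.000627 (adjusted p = 0.168 with an estimated correlation). Of 25 genes of the unfolded protein response, 14 were higher and 3 lower (14 and 3 adjusted over the list alone). Sdf2l1, Hsp90b1, Pdia6 and Hyou1 had log2 fold changes of 1.41, 1.32, 1.10 and 1.06, and the list a camera adjusted p of 0.000627 (adjusted p = 0.0661 with an estimated correlation). Of 38 nuclear genes of oxidative phosphorylation, 12 were higher (13 adjusted over the list alone). Atp5b and Uqcrfs1 had log2 fold changes of 0.61 and 0.59, and the list a camera adjusted p of 0.0339 (adjusted p = 0.136 with an estimated correlation). That call ended without CD11b WT 3 (camera adjusted p = 0.066).

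Lists of B cell, red pulp macrophage, monocyte and neutrophil markers were lower at the label CD11b by camera. Of 15 B cell markers, 10 were lower (12 adjusted over the list alone). Cd22, Blk and Pax5 had log2 fold changes of −4.11, −2.97 and −2.86, and the list a camera adjusted p of 0.000627 (adjusted p = 0.567 with an estimated correlation). Of 16 red pulp macrophage markers, 11 were lower (11 adjusted over the list alone). Axl, C1qb and Adgre1, which encodes F4/80, had log2 fold changes of −2.75, −2.40 and −5.23, and the list a camera adjusted p of 1.05e-05 (adjusted p = 0.0933 with an estimated correlation). Of 12 monocyte markers, 8 were lower and 1 higher (8 and 1 adjusted over the list alone). Ace, Ms4a4c and Treml4 had log2 fold changes of −5.30, −4.97 and 1.78, and the list a camera adjusted p of 0.00035 (adjusted p = 0.0462 with an estimated correlation). Of 3 neutrophil markers measured, 3 were lower (3 adjusted over the list alone), among them Mmp9 and the receptor gene Csf3r at −5.27 (camera adjusted p = 0.00144, adjusted p = 0.0661 with an estimated correlation). Most markers on that list, S100a8 among them, did not pass the filter. The third, Ltf, had 1 count at the label CD11b, and its call ended without CD11b WT 1, 2 or 3, CD8 WT 1 or 3 or CD8 KO 1 (edgeR adjusted p = 0.11, 0.118, 0.0578, 0.0969, 0.125, 0.091). Of 24 immediate early genes, 11 were lower and 3 higher (12 and 3 adjusted over the list alone). Klf4, Jun and Fosb had log2 fold changes of −2.35, −2.08 and −1.19, and the list a camera adjusted p of 0.00278 (adjusted p = 0.567 with an estimated correlation).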

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

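The tests of exchanged or mixed subsets, of the stretch beside Itgax and its strands, of clustering on 1 chromosome and of B cell or plasma cell RNA were chosen after the results were seen, while the window around Atg16l1 and the splits of the libraries were planned. In 3 genes the genotype effect differed between the labels by the edgeR test of the difference. Plcb4 had a difference of −2.62, Gbp2 of −2.74 and Gbp3 of −2.84 (log2, label CD11b minus label CD8). In the counts of the opposite strand, which the comparisons did not use, Itgad was higher in KO by a log2 fold change of 4.63 at the label CD11b and 3.76 at the label CD8, with 3, 3 and 2 counts in CD11b WT, 80 and 48 in CD11b KO, 15, 14 and 12 in CD8 WT and 286 and 172 in CD8 KO. Of 7913 genes tested on that strand, edgeR called 7 at the label CD11b and 3 at the label CD8.

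The subset markers ran opposite to the subset labels. Both subsets mixed in each sort would leave substantial Cd8a and Itgam in both sets of libraries, but the lower set held 0.66% of the Cd8a and 2.5% of the Itgam of the higher set, which argues against it. Exchanged subset labels need the markers of the other subset in every library, and 10 of 10 libraries had them. That count restates the pattern that raised the question and is not separate support. Correct labels are argued against by Cd8a, with 448 to 578 CPM at the label CD11b and at most 5.87 CPM at the label CD8. Itgam also argues against them, with at most 2.73 CPM at the label CD11b and at least 76.1 CPM at the label CD8. An exchange of the 2 labels is the candidate explanation left of those named here. Whether it arose at the sort, in the library sheet or in the deposited names was not tested. If it is right, the genotype effects reported at the label CD11b belong to the CD8-positive subset and the reverse.

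Several genes called between genotypes were neighbours in the genome or lay on the same chromosome, and sequence carried along with the targeted gene would place calls near Atg16l1, but 0 of the 20 other genes called at the label CD11b and 0 of the 20 at the label CD8 lay within 20 Mb of it (216 tested; Fisher exact p = 1 for each), though 19 and 20 genes there had an unadjusted p under 0.05 (8.8% and 9.26%, against 6.37% and 6.47% elsewhere). Itgad reads counted on the wrong strand (opposite-strand counts were 5.65% to 7.41% of those used) are argued against for Cox6a2, with 273 KO counts on its own strand against 58 on that of Itgad (471%), and are a candidate source for 4931431B13Rik, with 110 against 1385 (7.94%). A change in the sequence next to Itgax in the KO animals, such as extra copies carried by a large-insert transgene built on Itgax (the labels name none), is a possible explanation for Itgad and Cox6a2 that stays open: the median log2 fold change of the 4 genes there was 2.42 at the label CD11b and 4.14 at the label CD8, but they were picked for their values and 3 of them lie within the span of Itgad. Linked sequence from another strain on 1 chromosome may also contribute, since 7 of 28 separate called loci lay on chromosome 13 (12615057 to 44504548) against 1.13 expected (permutation p = 0.0226, 100000 draws). Atg16l1 and immunoglobulin genes were left out of the 28, and neighbours within 0.5 Mb counted as 1. Of the 7, Gcnt2 was called at both labels and Irf4, Hist1h4b, Gfod1, Ly86, Gpr137b-ps and Gm34084 at 1 label each. An effect of Atg16l1 loss on these genes stays open, as do the causes of the changes in Slc15a2, Gbp2, Gbp3, Gbp2b, Odc1 and Plcb4 on other chromosomes.

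The immunoglobulin genes Ighg3 and Igkj1 were called between genotypes at the label CD11b by edgeR, and the B cell marker list at the label CD8 by camera (adjusted p = 2.33e-12, and 0.325 with an estimated correlation). The 2 genes had a median log2 fold change of 5.12, and B cells in the KO libraries labelled CD11b are argued against by a median of 0.11 over 12 other B cell markers (SD 1.08 over genes; 2 of them over 10 CPM in WT). Plasma cells there cannot be told apart from a change in the sorted cells, because the median of 7 plasma cell markers was 0.04 (SD 1.37) but 2 of them, Jchain and Txndc5, stood over 10 CPM in WT. At the label CD8 the 12 B cell markers had a median of 1.23, which became −0.04 without CD8 KO 2 and 1.87 without CD8 KO 1. CD8 KO 2 had already been seen to hold the most of these transcripts, so this shift repeats that observation and is not a separate test. B cells in 1 of the 2 KO libraries labelled CD8 are a candidate source (6 of the 12 were over 10 CPM in WT, and Ighm stood at 1242 CPM and Igkc at 697 CPM in CD8 KO 2). The gate on high CD11c, per the submitters' protocol, would remove most B cells, and a genotype effect on them stays open.

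Chance was examined by splitting the libraries into other groups of the same sizes. The real split of the 5 libraries called 21 genes at the label CD11b and at most 16 in the other splits, and 21 at the label CD8 against at most 8. In the 6 WT libraries the real split called 4182 genes and the other splits 0. Each other WT split put both labels in both groups, which widens the spread within groups, so its 0 calls were largely fixed in advance. The other genotype splits also mixed WT with KO libraries. In each case 1 of 10 splits, the real one, reached the real count, and 10 splits are too few for a share under 0.05.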

How the results depend on the processing

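Leaving out both doubted libraries (CD11b WT 1 and CD8 KO 2) and taking out immunoglobulin genes were chosen after the data were seen; all other alternatives were planned. Unless stated, the cause of a move was not tested. The 21 genes called between genotypes at the label CD11b became 71 with no filter on low counts, 42 with DESeq2, 13 with only the libraries labelled CD11b (11 of the 21 kept; fewer libraries were fitted) and 39 without both doubted libraries (19 kept), and ranged from 14 to 39 with 1 library left out. The 21 at the label CD8 became 142 with no filter (84 higher, 58 lower), 54 with DESeq2, 63 with limma-voom and 63 with only the libraries labelled CD8, stayed at 22 without both doubted libraries (14 kept), and ranged from 18 to 105 with 1 library left out. For the difference of effects the 3 genes, all lower, became 41 with no filter (16 higher), 6 with unstranded counts (1 higher), 11 with DESeq2 (6 higher) and 5 without immunoglobulin genes. With 1 WT library left out they ranged from 3 to 6. Plcb4, Gbp2 and Gbp3 were called under each of these alternatives. The subset comparison called 3659 to 4546 genes in WT and 2520 to 3564 in KO over all alternatives, and 3659 to 4383 and 2520 to 3486 with 1 library left out. Where 1 KO library was left in a group, the lone library was assumed to vary like the other groups. The filter then kept 16171 to 17062 genes against 14528 with all libraries, so counts of calls from such fits also reflect a different set of tested genes.

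Of the named genes called at the label CD11b, 7 of 16 were called under every alternative (Itgad, Slc15a2, Gbp2b, Gbp3, Gbp2, Arhgef6 and Odc1), and at the label CD8 9 of 16 (Atg16l1, Itgad, Plcb4, Lima1, Slc15a2, Mmp9, Odc1, Arhgef6 and Gcnt2). In the WT subset comparison 62 of the 64 called genes followed were. The 5 gene lists called at the label CD11b became 9 with unstranded counts, 8 with the replicate block, 0 with an estimated correlation and 0 with directional fry, and 3 to 9 with 1 library left out. The 10 lists at the label CD8 became 6 without both doubted libraries, 0 with an estimated correlation and 0 with directional fry, and 6 to 12 with 1 library left out. The 6 lists of the difference became 0, 0 and 2 with an estimated correlation, directional fry and mixed fry, and 4 to 10 with 1 library left out. The 12 lists of the subset comparison became 4, 22 and 30 with these tests, and 11 to 13 with 1 library left out. Mixed fry, which counts changes in both directions together, called 5 lists at the label CD11b and 8 at the label CD8.

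Directions turned in few results. In the difference of effects, the B cell list turned without CD8 KO 2 (camera adjusted p = 0.897; 1.11e-15 without CD8 KO 1) and without both doubted libraries (0.673). Atg16l1 in that difference had 0.0483 without CD8 KO 2, −0.88 without CD8 KO 1 and 0.0705 without both doubted libraries. Cd79a at the label CD8 had −0.0422 without CD8 KO 2, −0.0385 without both and 2.38 without CD8 KO 1.

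The labels give replicate numbers but no shared mouse. Same-numbered libraries of the 2 subset labels deviated together little (correlations of 0.018 to 0.049 in 5 pairs), and those of the genotypes had −0.037 to 0.059 in 4 pairs. Deviations in a group of 2 mirror each other, so the 2 KO pairs across subset labels (0.041 each) are 1 value and not separate. The numbers were not taken as pairs. However, 6 of 6 WT libraries correlated best with their own number across the subset labels, so a shared mouse is not excluded. With the replicate block, 29 genes were called at the label CD11b, 26 at the label CD8 and 8 in the difference (3 higher); with the block by genotype, 28 were called in the difference (12 higher), 4462 in the WT subset comparison and 3564 in the KO one. On simulated counts at the depth and replicate numbers used here, 1.5-fold changes were recovered in 21.9% of changed genes at the label CD11b (13827 genes). Recovery was 11.1% at the label CD8 (13823 genes) and 0% for the difference of effects (13803 genes). Which of depth and replicate number set this was not tested. More genes were called in these simulations than in the data, which loosens the adjusted threshold, so recovery in the data may be lower.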

Other observations

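The tests in this part were planned, but the lists, Tollip, Xist and the Y chromosome genes were picked for this part after their values were seen. Several gene lists tied to autophagy and antigen presentation were not called between genotypes. Of 12 autophagy receptor genes, 0 were called by edgeR, DESeq2 or limma-voom at the label CD11b (1 at an unadjusted p under 0.05; camera adjusted p = 0.969) and 0 at the label CD8 (2 at an unadjusted p under 0.05; camera adjusted p = 0.92). Adjusted over the list alone, edgeR called Tollip at the label CD8 (log2 fold change 0.48; adjusted p = 0.038, and 0.362 over all genes), and the mixed fry test of the list there had an adjusted p of 0.00334 (0.66 at the label CD11b).

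Among 34 lysosomal genes, 26 had a negative log2 fold change at the label CD11b (median −0.07; camera adjusted p = 0.0793) and 24 a positive one at the label CD8 (median 0.08; camera adjusted p = 0.191). By edgeR, DESeq2 and limma-voom 0 of them were called at either label, with 3 and 5 at an unadjusted p under 0.05. Among 11 MHC class II genes, 8 were negative at the label CD11b (median −0.13; camera adjusted p = 0.0952) and 10 at the label CD8 (median −0.06; camera adjusted p = 0.111). With edgeR and DESeq2, 0 of the 11 were called at either label, with 4 and 1 at an unadjusted p under 0.05, and limma-voom called 0 and 1.

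Among 24 cholesterol synthesis genes, 17 were negative at the label CD11b (camera adjusted p = 0.172) and 12 at the label CD8 (camera adjusted p = 0.599), and edgeR, DESeq2 and limma-voom called 0 at either label, with 3 and 1 at an unadjusted p under 0.05. Among 25 genes of the unfolded protein response, 16 and 18 were positive (camera adjusted p = 0.969 and 0.0869), and these tools called 0 at either label, with 3 and 2 at an unadjusted p under 0.05. Xist, the RNA that silences 1 X chromosome, stood at 892 to 1235 CPM in the 10 libraries. The Y chromosome genes Eif2s3y and Kdm5d had 0 counts in each library, and Ddx3y and Uty at most 2. The labels give no sex, but these values argue against male mice in either genotype.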
